A study of Mus musculus with 6 samples.

How the data were processed

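RNA from 3 Bcat1-knockout and 3 control samples of the mGB2 line was sequenced after column extraction with DNase treatment and a stranded poly(A) library preparation, per the labels' protocols. Reads were aligned with STAR 2.5.3a to mm10 and counted with featureCounts, per the submitters' processing notes, while the annotation release is not given in the sources used here. Each deposited table lists 49585 genes with coordinates, exonic length, counts and normalized values, per the file headers. The deposited read counts are raw numbers of reads per gene, given without regard to strand, on the forward strand and on the reverse strand. Between 96.4% and 96.5% of the stranded reads lay on the reverse strand, as the kit gives, and these counts were used for the main test. The authors' TPM values, scaled over all genes of a library, were used for an alternative. A further TPM column, treated as a score, has a denominator that leaves out chromosomes MT, X and Y in the deposited files, as the values show, and served only to check that.

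Gene IDs were matched by stable ID to GENCODE M21 for the gene type alone, and 49326 IDs (99.5%) were found. Coordinates are those of the deposited tables in mm10.

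Libraries held 29543157 to 37800648 counts, so 3 counts correspond to 0.0794 to 0.102 CPM in 1 library. Genes were kept with edgeR 4.0.16's expression filter, which left 14020 genes and removed 0.0511% of the counts. Counts were scaled by the TMM method, and knockout was compared with control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, with no covariate. CPM values are scaled by TMM. Where a group had 0 counts, the fold is a bound against 3 counts over the group, and where it had 1 to 3 counts the ratio has an exact 95% interval. The rule for named genes was fixed before the data were examined. It took Bcat1, then the 10 genes higher and 10 lower with the largest change among those past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, leaving out predicted models and pseudogenes. It added the 4 most abundant genes in each direction with a log2 fold change of at least 1, and up to 4 members of each list. The list members were those with the largest change among those past the threshold with a mean log2 CPM of at least 0. Some genes that this rule takes are not reported here.

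The 24 gene lists were also fixed before the data were examined and were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry. List medians were equal with genes at 0 in a group set to their bound. Alternatives were 2 other scalings, no filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), unstranded counts, a test against a 1.5-fold threshold, a replicate block, a gene length offset, both together, leaving out mitochondrial and the 10 most abundant genes, and leaving out each replicate. After the data were seen, a fit without the chromosome 7 and 12 stretches and a fit with the local median of 51 neighbouring genes removed were added.

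The test was run on simulated counts with the means and depths of these libraries (13805 genes). It recovered 34%, 58%, 92% and 94% of 50 genes changed by 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 9.74% of its calls were unchanged genes. Only 50 genes were changed at each fold, whereas 62.3% of tested genes changed in the data. Adjusted p-values depend on that share, so these rates need not hold for the real comparison. In the simulation 2 of 2 shifted lists were recovered and 0 unshifted lists were called. Its genes were drawn independently of each other, so it cannot show how the list test behaves when genes are correlated. Replicate pairs of a group differed beyond counting noise, with a chi-square per gene of 4.60 to 39.4, so no library was counted as a duplicate. A multidimensional scaling plot of edgeR log values used distances over the genes that differed most between each pair of libraries. Its first dimension held 93.5% of the variance of those distances and separated the groups. Bcat1-KO replicate 1 lay apart from the other knockout libraries on the second dimension. No sample was left out of the comparison. Analyses used R 4.3.3 and Python 3.11.15.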

Results

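RNA was measured in mGB2, a mouse glioblastoma cell line that its labels describe as glioblastoma stem cells, in 3 libraries from Bcat1-knockout cells and 3 from control cells. Bcat1 encodes the cytosolic aminotransferase that takes the amino group from leucine, isoleucine and valine and passes it to 2-oxoglutarate, giving glutamate. The cells were untreated and had been cultured as an attached layer on matrix-coated plates in serum-free stem cell medium with EGF and FGF, and RNA was taken at confluency. The libraries held 35608024, 37800648 and 36414678 strand-matched gene counts in the knockout and 31606648, 33550412 and 29543157 in the control. Mitochondrial genes took between 1.31% and 2.28% of the counts, with the highest share in control replicate 1. The title of the series names cell plasticity and immunosuppression as the processes in question, and the comparison of knockout with control asks which genes differ when Bcat1 is targeted. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which can be technical.

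Bcat1 (ENSMUSG00000030268.17, protein coding, chromosome 6 from 144993835 to 145076184 in mm10) was still transcribed in the knockout libraries. Its level was 168 ± 11.5 CPM in the knockout and 223 ± 9.26 CPM in the control (mean ± SD, n = 3 each), and every knockout library lay below every control library. The knockout libraries held 155, 176 and 173 CPM, and the control libraries 214, 223 and 232 CPM. The log2 fold change was -0.41 (SE 0.07, adjusted p = 0.000355, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It was -0.55 with a gene length offset and -0.65 with the local median of 51 genes removed. The counts are sums over the whole gene, so they do not show whether an edited exon was present, and a knockout need not remove the mRNA. It did not pass edgeR's test against a 1.5-fold threshold (adjusted p = 1). Bcat2, which encodes the mitochondrial enzyme of the same reaction, fell from 127 ± 7.11 to 53 ± 2.65 CPM (log2 fold change -1.26, SE 0.07, adjusted p = 1.83e-08, edgeR).

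**Figure D1:**
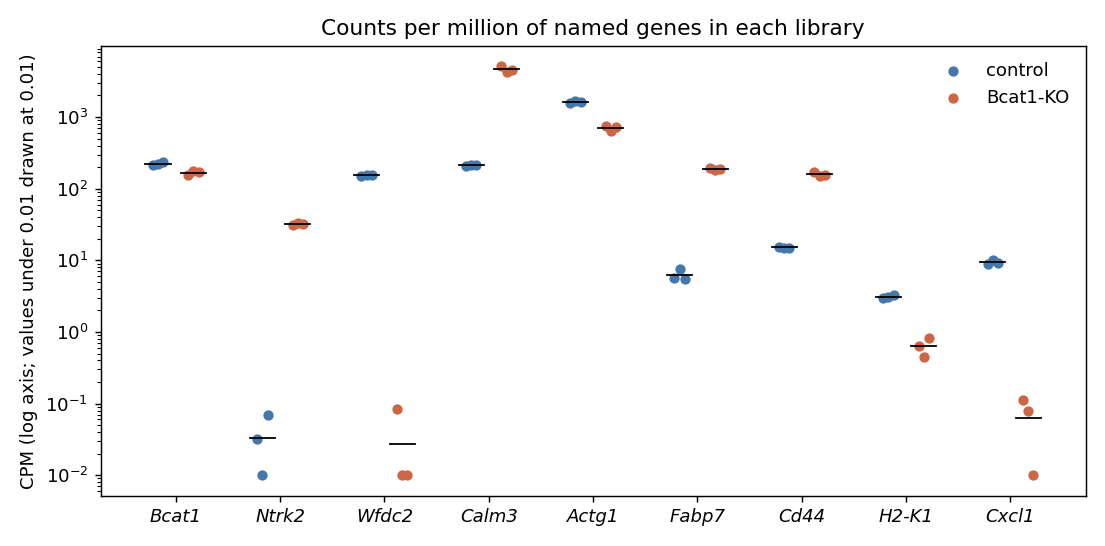
CPM (log axis) of 9 genes in each of the 3 control and 3 knockout libraries, with 1 point per library and a black line at the group mean. Bcat1 lies between 155 and 176 CPM in the knockout and between 214 and 232 CPM in the control, whereas Ntrk2 and Wfdc2 are near 0 in one of the groups.

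Among the 24 lists fixed beforehand, of which 0 passed a camera test with an estimated correlation between genes, 17 of 25 neural stem and progenitor genes were higher in the knockout and 2 lower, and 19 of 26 astrocyte markers were higher and 3 lower. In the other direction, 14 of 17 genes of MHC class I antigen presentation were lower and 0 higher, with 4 H2 genes among the lower ones. Of the matrix genes, 16 of 26 were lower and 7 higher, and of the immediate early genes 13 of 20 were lower and 1 higher. Of 14020 genes tested, 8735 (62.3%) changed, 4480 higher and 4255 lower in the knockout (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold were found for 1369 higher and 1322 lower genes, and changes of at least 4-fold for 691 and 552. The knockout and control values did not overlap for 9489 genes, or 67.7% of those tested, where chance gives 10%. The common biological coefficient of variation between replicates was 8.26%. In a test against a 1.5-fold threshold, 1564 genes were higher and 1481 lower.

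Several genes were present in one group and at or near 0 in the other. Col4a5, a chain of basement membrane collagen (ENSMUSG00000031274.16, chromosome X from 141475385 to 141689234), had 0 counts in the control and 27.3 ± 2.24 CPM in the knockout, which is at least 849-fold higher against a floor of 3 counts over the control group. Chrdl1, a BMP antagonist, was at least 634-fold higher, Grik3, a kainate-type glutamate receptor subunit, at least 369-fold, and St6gal2, a sialyltransferase, at least 344-fold. Ntrk2, the receptor for BDNF (ENSMUSG00000055254.14, chromosome 13 from 58806596 to 59133970), had 3 counts over the control group and 32.1 ± 0.698 CPM in the knockout, a ratio of 1002 with a lower exact 95% bound of 343. Galm, a galactose mutarotase, had 2 control counts and 11.2 ± 2.71 CPM in the knockout. Astn1, Gria4 and Sema5a had means below 0.1 CPM in the control and reached 72.0 ± 7.24, 35.5 ± 4.01 and 28.9 ± 4.59 CPM. Psg29 was at least 3730-fold higher, from 0 control counts to 119 ± 11.2 CPM. It belongs to a family of similar genes, between which the counting can divide reads, and lies in a stretch of chromosome 7 whose genes rose together.

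Wfdc2, a secreted protease-inhibitor-like protein (ENSMUSG00000017723.11, chromosome 2 from 164562413 to 164568510), fell from 154 ± 3.92 CPM to 3 counts over the knockout group, a ratio of 5691 with a lower exact 95% bound of 1947. Smim20, Phyh and Dnajc15, whose products work in mitochondria or, for Phyh, in peroxisomes, had 0 counts in the knockout and were at least 393-fold, 388-fold and 313-fold lower. Rassf9 and Bcl11a, a transcriptional repressor, had 1 and 2 counts over the knockout group against 16.7 ± 1.2 and 23 ± 1.58 CPM in the control. Plp2, Rbfox3, Fetub and Ptgr2 had means below 0.1 CPM in the knockout, against 59.8 ± 3.67, 33.1 ± 0.667, 27.2 ± 1.13 and 13.5 ± 1.26 CPM in the control. Intervals and floors cover counting error only.

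Among abundant genes, cytoplasmic gamma-actin (Actg1) fell from 1622 ± 53.3 to 706 ± 60.9 CPM, the endoplasmic reticulum chaperone gene Hsp90b1 from 1264 ± 46.3 to 628 ± 38.6 CPM, Nbas from 1186 ± 64.1 to 317 ± 16.1 CPM and Cyb5r1 from 946 ± 29.8 to 470 ± 135 CPM. The knockout libraries held 317, 571 and 523 CPM of Cyb5r1, and its log2 fold change was -1.01, or -0.56 with the local median of 51 genes removed. Mtss1l rose from 461 ± 8.66 to 1016 ± 90.3 CPM. Calm3, which encodes calmodulin (chromosome 7 from 16915379 to 16924114), rose from 212 ± 4.74 to 4644 ± 427 CPM, with a log2 fold change of 4.46 (SE 0.10, adjusted p = 1.47e-11, edgeR). Strn4 rose from 149 ± 5.24 to 1495 ± 56.3 CPM and the phosphatase gene Ppp5c from 156 ± 3.12 to 1302 ± 67.1 CPM. Calm3, Strn4 and Ppp5c lie in the chromosome 7 stretch, and Nbas in a chromosome 12 stretch. Calmodulin is encoded by several similar genes, so a part of the Calm3 reads is uncertain.

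Neighbouring genes on chromosome 7 rose together. In the stretch from Tmem160 to Psg29 (16452779 to 17215760, mm10), 19 of 21 tested genes were higher and 0 lower, with a median log2 fold change of 2.55. All 12 members with at least 10 CPM in the control were higher, by log2 fold changes of 0.20 to 4.46. The 40 flanking genes had a median of -0.08. The stretch took 0.984% of the counts in the knockout and 0.11% in the control. On chromosome 12, Mycn, Ddx1 and Nbas (12936096 to 13583810) were abundant in both groups and lower in the knockout. The proto-oncogene Mycn went from 950 ± 14.7 to 726 ± 60.2 CPM, and the RNA helicase gene Ddx1 from 7254 ± 257 to 3661 ± 298 CPM. From Greb1 to Hpcal1 (16670615 to 17791926), 10 of 11 genes were higher, with a median of 1.42. Odc1, the rate-limiting enzyme of polyamine synthesis, rose there from 316 ± 12.6 to 845 ± 95.8 CPM. These stretches, Mycn, Ddx1 and Odc1 were chosen after their values were seen.

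**Figure D2:**
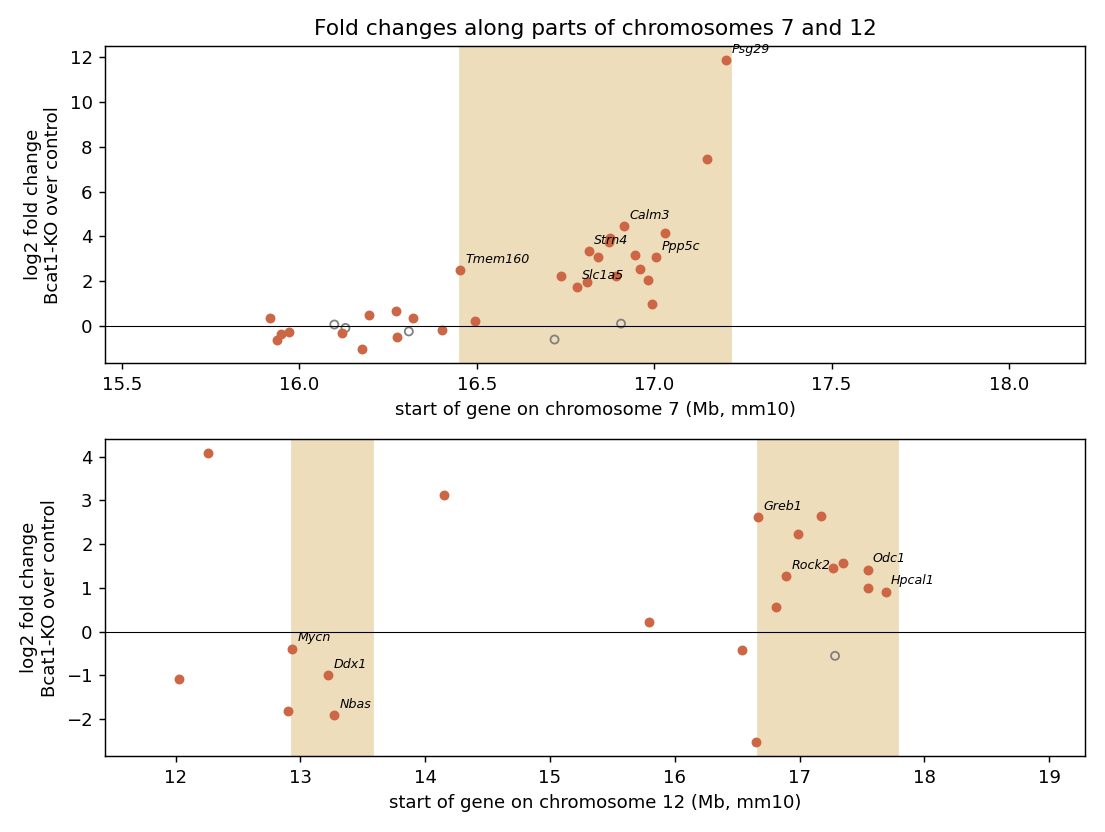
Log2 fold change of each tested gene, knockout over control, against its start (Mb, mm10) on parts of chromosome 7 (top) and chromosome 12 (bottom), with the stretches shaded, filled points past the threshold and genes with 0 counts in a group drawn at their bound. Of the 21 genes of the chromosome 7 stretch, 19 are higher, and Mycn, Ddx1 and Nbas lie below 0.

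Of 24 gene lists fixed before the data were examined, 11 passed the camera test with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p under 0.05), 6 higher and 5 lower. With an estimated correlation 0 of the 24 passed, with a smallest adjusted p of 0.215, 4 lists under an unadjusted p of 0.05 and 17 lists past the threshold with fry. Another grouping of the 6 libraries into 3 and 3 had 12 lists past the threshold. The counts adjusted over the list alone were equal for 20 lists and are given beside the other 4.

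Neural stem and progenitor genes were higher, 17 of 25 tested members against 2 lower (camera adjusted p = 2.77e-08, adjusted p = 0.215 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, rose from 6.27 ± 1.10 to 188 ± 3.54 CPM. The hyaluronan receptor gene Cd44 rose from 15.2 ± 0.233 to 161 ± 10.5 CPM and the Notch target Hes5 from 5.59 ± 0.832 to 52.0 ± 7.72 CPM. Of the astrocyte markers, 19 of 26 were higher and 3 lower (camera adjusted p = 0.00109, adjusted p = 0.329 with an estimated correlation). The glutamate transporter gene Slc1a2 rose from 0.738 ± 0.114 to 12.4 ± 0.879 CPM, and Aqp4 and Gpr37l1 rose from means below 0.1 CPM to 3.90 ± 1.80 and 1.84 ± 0.771 CPM. Clu went the other way, from 13.4 ± 0.885 to 1.32 ± 0.301 CPM. In the oligodendrocyte lineage list, 10 of 16 were higher and 2 lower (camera adjusted p = 0.00188, adjusted p = 0.271 with an estimated correlation). Ptprz1 rose from 35.2 ± 2.58 to 364 ± 72.8 CPM, Cspg4 from 9.63 ± 0.68 to 55.6 ± 9.85 CPM, Sox8 from 37.4 ± 1.24 to 186 ± 21.2 CPM and Olig1 from 82.9 ± 6.73 to 327 ± 16.8 CPM. Of the neuronal markers, 12 of 20 were higher and 4 lower, and the list did not pass (camera adjusted p = 0.472). It held both Gria2, which rose from 0.116 ± 0.0966 to 19 ± 5.12 CPM, and Rbfox3, which fell. Elavl2 rose from 7.15 ± 0.478 to 28.0 ± 0.861 CPM and Dcx from 0.444 ± 0.189 to 1.73 ± 0.0256 CPM.

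**Figure D3:**
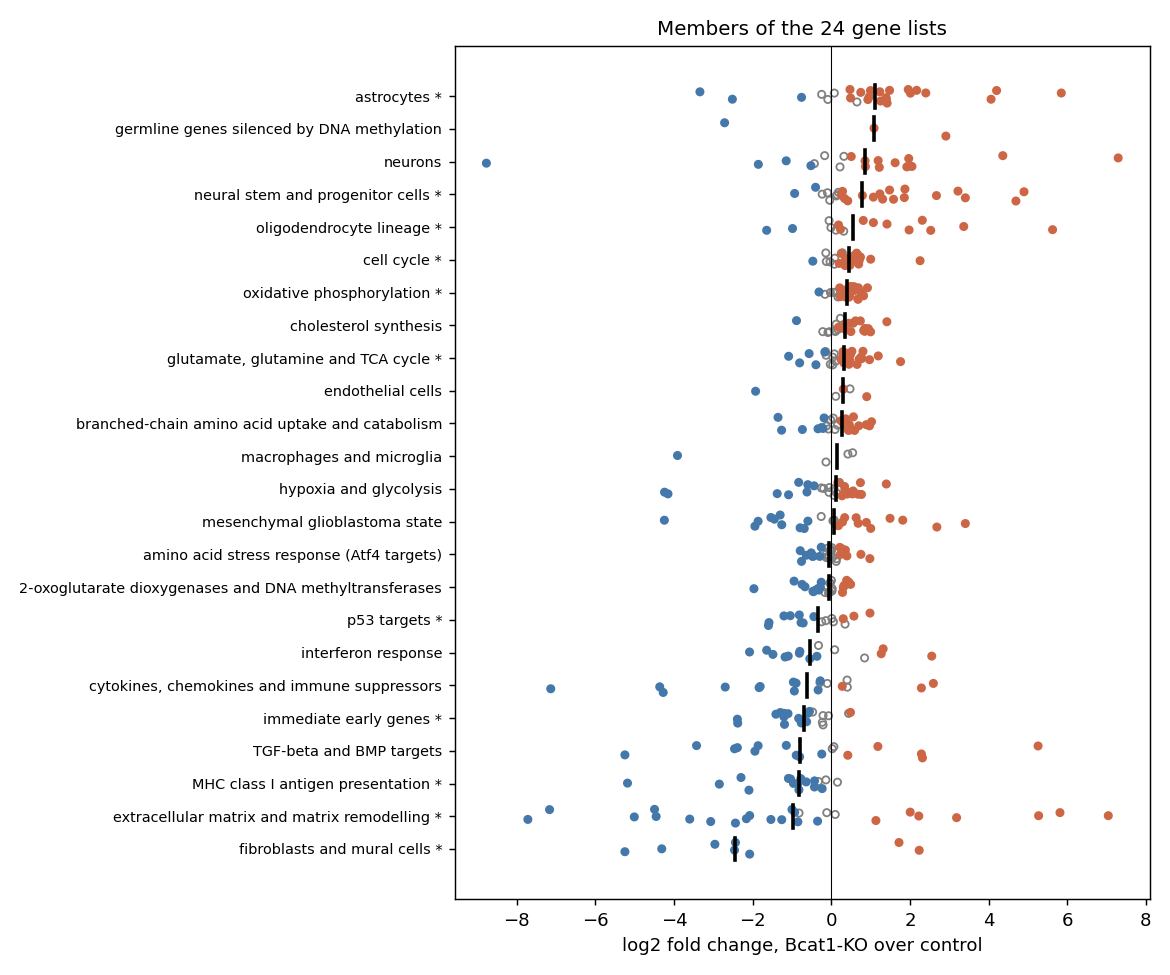
Log2 fold change, knockout over control, of every tested member of the 24 gene lists, ordered by the list median (black bar), with filled points past the threshold, open points not past it, and genes with 0 counts in a group drawn at their bound. An asterisk marks the 11 lists past the camera test with the preset correlation, of which 0 passed with an estimated one.

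The mesenchymal glioblastoma list split, with 11 of 25 genes higher and 10 lower (camera adjusted p = 0.782). Besides Cd44, the metallothionein gene Mt2 rose from 3.28 ± 0.487 to 21.1 ± 3.40 CPM, whereas S100a6 fell from 3.31 ± 0.216 to 0.172 ± 0.0366 CPM and Tgfbi from 18.0 ± 0.859 to 4.68 ± 1.47 CPM. Its mean log2 fold change was -0.09 while its median was 0.07 and its camera direction was up. Extracellular matrix genes were lower, 16 of 26 against 7 higher (camera adjusted p = 0.0108, adjusted p = 0.729 with an estimated correlation). Mmp2, a gelatinase, fell from 138 ± 1.67 to 0.958 ± 0.113 CPM, and the thrombospondin gene Thbs1 from 2.67 ± 0.573 CPM to 1 count over the knockout group. The membrane-bound protease gene Mmp14 rose from 0.198 ± 0.147 to 27.2 ± 1.76 CPM and the basement membrane collagen gene Col4a1 from 6.84 ± 0.633 to 385 ± 45.2 CPM. Without Bcat1-KO replicate 2 the list did not pass (adjusted p = 0.0815, in a range of 0.00303 to 0.0815 over 19 settings).

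Markers of fibroblasts and mural cells were lower for 6 of 8 tested members and higher for 2 (camera adjusted p = 0.00188, adjusted p = 0.271 with an estimated correlation). Col3a1 fell from 60.4 ± 1.86 to 11.2 ± 0.397 CPM, Pdgfrb from 4.54 ± 0.0349 to 0.224 ± 0.0872 CPM, Acta2 from 2.88 ± 0.314 to 0.0714 ± 0.0393 CPM and Myh11 from 2.06 ± 0.32 to 0.261 ± 0.0613 CPM. Col1a2, Dcn and Lum, which fibroblasts express strongly, had means below 1 CPM in both groups. Of 17 TGF-beta and BMP targets, 10 were lower and 5 higher (camera adjusted p = 0.495). Ctgf fell from 3.43 ± 0.627 to 0.311 ± 0.181 CPM and Junb from 30.8 ± 2.34 to 5.88 ± 0.229 CPM, whereas the BMP receptor gene Bmpr1b rose from 0.396 ± 0.105 to 15.2 ± 1.24 CPM. Immediate early genes were lower for 13 of 20 members and higher for 1 (camera adjusted p = 0.00133, adjusted p = 0.312 with an estimated correlation). Besides Junb, Zfp36 fell from 16.1 ± 0.492 to 6.05 ± 0.297 CPM, Ier3 from 75.8 ± 4.01 to 30.8 ± 1.16 CPM and Jund from 110 ± 6.11 to 47.5 ± 4.72 CPM, with a log2 fold change of -1.21 for Jund, or -0.80 with the local median of 51 genes removed.

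Genes of MHC class I antigen presentation were lower for 14 of 17 members and higher for 0, or 15 lower when adjusted over the list alone (camera adjusted p = 0.00188, adjusted p = 0.329 with an estimated correlation). H2-T23 fell from 1.84 ± 0.214 to 0.253 ± 0.067 CPM, H2-K1 from 3.12 ± 0.131 to 0.635 ± 0.192 CPM and H2-D1 from 6.57 ± 0.312 to 1.54 ± 0.282 CPM. The levels of these H2 genes were low in both groups, and similar H2 genes can share reads. Tapbpl, a peptide editor, fell from 1.57 ± 0.152 to 0.738 ± 0.212 CPM. Of 15 interferon response genes, 9 were lower and 3 higher, or 4 higher when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.406). Ifi35 fell from 9.75 ± 0.385 to 3.49 ± 0.673 CPM, Irf9 from 11.5 ± 0.921 to 5.07 ± 1.08 CPM and Ifi27 from 18.2 ± 0.304 to 10.4 ± 1.10 CPM, while Rsad2 rose from 0.936 ± 0.145 to 5.53 ± 2.04 CPM. The log2 fold change of Ifi27 was -0.81, or -0.34 with the local median of 51 genes removed. Of 18 cytokine, chemokine and immune suppressor genes, 11 were lower and 3 higher, and the list did not pass (camera adjusted p = 0.207), although it did with limma-trend on TPM (adjusted p = 0.0326), in a range of 0.0326 to 0.486 over 19 settings. The neutrophil attractant gene Cxcl1 fell from 9.37 ± 0.739 to 0.0629 ± 0.0569 CPM and the membrane-bound chemokine gene Cx3cl1 from 51 ± 2.66 to 14.5 ± 1.10 CPM. Tgfb2, an immunosuppressive cytokine gene, rose from 11.6 ± 1.22 to 56.9 ± 3.79 CPM and the alarmin gene Il33 from 2.38 ± 0.445 to 14.5 ± 3.0 CPM.

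Cell cycle genes were higher for 23 of 30 members and lower for 1 (camera adjusted p = 0.00938, adjusted p = 0.271 with an estimated correlation). The mitotic kinase gene Plk1 rose from 90.2 ± 5.95 to 181 ± 20.1 CPM, the kinesin gene Kif11 from 135 ± 4.31 to 225 ± 6.26 CPM, Rrm2 from 61.0 ± 5.82 to 99.9 ± 5.08 CPM and Ccnb2 from 0.495 ± 0.153 to 2.36 ± 0.293 CPM. Of 16 p53 targets, 8 were lower and 3 higher (camera adjusted p = 0.0361, adjusted p = 0.312 with an estimated correlation). Gadd45a fell from 136 ± 3.61 to 45.0 ± 0.683 CPM, Trp53inp1 from 58.9 ± 0.716 to 19.7 ± 0.955 CPM, Btg2 from 222 ± 14.5 to 96.3 ± 7.54 CPM and the death receptor gene Tnfrsf10b from 23.9 ± 0.559 to 11.6 ± 0.586 CPM. With the local median of 51 genes removed the log2 fold changes of Rrm2, Btg2 and Tnfrsf10b went from 0.71, -1.20 and -1.04 to 0.47, -0.76 and -0.58. The p53 list did not pass without Bcat1-KO replicate 2 (adjusted p = 0.0629), with limma-voom (adjusted p = 0.0621), with limma-trend on TPM (adjusted p = 0.0538) or with the local median of 51 genes removed (adjusted p = 0.116), in a range of 0.005 to 0.116 over 19 settings.

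Oxidative phosphorylation genes were higher for 20 of 26 members and lower for 1, or 21 higher when adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.729 with an estimated correlation). The complex III genes Uqcrc1 and Cyc1 rose from 152 ± 7.04 to 269 ± 10.7 CPM and from 187 ± 6.19 to 315 ± 45.0 CPM, and the respiratory chain genes Ndufa4 and Cox7a2 from 93.8 ± 6.62 to 177 ± 28.6 CPM and from 73.0 ± 6.16 to 118 ± 14.2 CPM. Bcat1-KO replicate 1 was highest for Cyc1, Ndufa4 and Cox7a2, with 366, 210 and 134 CPM against 281 and 298, 161 and 161, and 109 and 110 CPM in the other knockout libraries, and without it the list passed (adjusted p = 0.0285). With the local median of 51 genes removed the log2 fold changes of Ndufa4 and Cox7a2 went from 0.92 and 0.69 to 0.57 and 0.37. Genes of glutamate, glutamine and TCA cycle metabolism were higher for 20 of 32 members and lower for 5 (camera adjusted p = 0.0447, adjusted p = 0.729 with an estimated correlation). Idh3a rose from 91.0 ± 3.78 to 208 ± 1.19 CPM and Suclg2 from 105 ± 1.62 to 205 ± 47.0 CPM, while the pyruvate carboxylase gene Pcx fell from 16.2 ± 1.13 to 7.64 ± 0.578 CPM. The glutamine transporter gene Slc1a5, in the chromosome 7 stretch, rose from 243 ± 26.7 to 823 ± 78.7 CPM. This list did not pass without the chromosome 7 and 12 stretches (adjusted p = 0.0917), without control replicate 1 (adjusted p = 0.0616) or with a replicate block (adjusted p = 0.0598), in a range of 0.00515 to 0.0917 over 19 settings.

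Of 28 genes of branched-chain amino acid uptake and catabolism, 15 were higher and 7 lower (camera adjusted p = 0.616). Besides Bcat2, the amino acid transporter gene Slc43a1 fell from 15.4 ± 0.809 to 6.02 ± 0.81 CPM, while Slc43a2 rose from 1.45 ± 0.396 to 2.95 ± 0.192 CPM and Acat1 from 130 ± 3.48 to 255 ± 24.8 CPM. Of 27 genes of 2-oxoglutarate dioxygenases and DNA methyltransferases, 11 were lower and 7 higher, or 12 lower when adjusted over the list alone (camera adjusted p = 0.39). The prolyl hydroxylase gene P4ha2 fell from 23.6 ± 0.297 to 6.02 ± 1.2 CPM, Tet1 and Tet2, which encode 5-methylcytosine dioxygenases, from 54.2 ± 4.81 to 28.1 ± 4.25 CPM and from 48.4 ± 6.94 to 28.9 ± 0.281 CPM, and the histone demethylase gene Kdm5b from 204 ± 7.76 to 128 ± 5.13 CPM. The log2 fold change of Kdm5b was -0.67, or -0.16 with the local median of 51 genes removed, and it did not pass the test against a 1.5-fold threshold (adjusted p = 0.141). Of 30 Atf4 targets of the amino acid stress response, 7 were higher and 8 lower (camera adjusted p = 0.782). Pycr1 and the cystine transporter gene Slc7a11 rose from 67.1 ± 2.5 to 132 ± 22.6 CPM and from 83.2 ± 3.84 to 140 ± 16.7 CPM, whereas Ddit3 fell from 201 ± 3.40 to 116 ± 15.1 CPM and Cebpb from 44.1 ± 1.31 to 26.1 ± 4.84 CPM. The log2 fold change of Ddit3 was -0.79, or -0.30 with the local median of 51 genes removed.

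Of 28 hypoxia and glycolysis genes, 12 were higher and 8 lower (camera adjusted p = 0.782). Car9, a carbonic anhydrase gene, fell from 23.1 ± 2.59 to 1.29 ± 0.231 CPM, Adm from 2.80 ± 0.36 to 0.145 ± 0.0438 CPM and Ankrd37 from 8.19 ± 1.40 to 3.16 ± 0.571 CPM, while Aldoc rose from 167 ± 17.2 to 440 ± 16.9 CPM. The median log2 fold change of this list was 0.11, its mean -0.24 and its camera direction down. Of 23 cholesterol synthesis genes, 14 were higher and 1 lower, and the list did not pass (camera adjusted p = 0.246), although it did with limma-voom (adjusted p = 0.0326) and with limma-trend on TPM (adjusted p = 0.0346), in a range of 0.0326 to 0.423 over 19 settings. Insig1 rose from 56.9 ± 4.61 to 152 ± 58.4 CPM and Tm7sf2 from 8.74 ± 0.377 to 17.5 ± 3.86 CPM. Dhcr7 rose from 36.0 ± 1.07 to 69.1 ± 24 CPM, with a log2 fold change of 0.94 that was 0.60 without Bcat1-KO replicate 1. That library was highest for Insig1, Tm7sf2 and Dhcr7, with 219, 21.9 and 96.8 CPM. The other knockout libraries held 124 and 112, 15.5 and 14.9, and 57.0 and 53.6 CPM.

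Of 3 tested germline genes silenced by DNA methylation, 2 were higher and 1, Taf7l, fell from 1.91 ± 0.101 to 0.286 ± 0.157 CPM (camera adjusted p = 0.909). Of 4 tested macrophage and microglia markers, 0 were higher and 1, Cd14, fell from 0.602 ± 0.161 to 0.0367 ± 0.042 CPM (camera adjusted p = 0.782). The median log2 fold change of those 4 was 0.14, their mean -0.77 and the camera direction down. Of 5 tested endothelial markers, 2 were higher and 1 lower (camera adjusted p = 0.797), with a median of 0.31, a mean of -0.03 and the camera direction up. Egfl7 rose from 4.55 ± 0.281 to 8.51 ± 1.40 CPM. Ramp2 went from 27.9 ± 0.904 to 34.6 ± 3.86 CPM, with a log2 fold change of 0.31 that was 0.19 without Bcat1-KO replicate 1.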

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

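The tests in this part were chosen after the data were seen. Counts on the strand opposite to each gene, which the comparison did not use, differed between the groups. Of 485 genes with no annotated gene on the opposite strand within 5000 bp, 47 had more such counts in the knockout than in the control and 34 had fewer (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The sense strand was also tested for 70 of the changed genes, and it changed the same way for 55 of them. It changed the opposite way for 5 genes, Greb1, Atp1b2, Ddx1, Gpr162 and Slc43a1. For Greb1, opposite-strand counts went from 1.60 ± 0.42 to 0.224 ± 0.0764 CPM while the sense strand rose from 32.7 to 201 CPM. For Ddx1 they went from 5.70 ± 0.949 to 12.1 ± 1.60 CPM while the sense strand fell from 7254 to 3661 CPM. No explanation was tested for these opposite-strand counts.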

How the results depend on the processing

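The alternatives were fixed before the data were examined, except the fit without the chromosome 7 and 12 stretches and the fit with the local median removed. The counts of changed genes stayed within 1.5 times of the 4480 higher and 4255 lower genes in every setting but the test against a 1.5-fold threshold, which called 1564 and 1481 because it asks for larger changes. Leaving out each replicate gave 3871 to 4589 higher and 3846 to 4741 lower genes. With the local median removed 3929 were higher and 3870 lower, and 76.3% of the original calls were shared, 58 of them with the opposite sign. Bcat1 kept its direction throughout, with log2 fold changes of -0.45 to -0.37 when a replicate was left out. It was -0.55 with a gene length offset and -0.65 with the local median removed. Against the 1.5-fold threshold its log2 fold change of -0.41 did not pass (adjusted p = 1), by the construction of that test.

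The number of lists past the threshold was 11, and 9 to 11 when a replicate was left out. It was 0 with an estimated correlation and 17 with fry, which tests whether the genes of a list move and does not compare them with other genes. The test against a threshold gives no list test. Among single list tests, 471 comparisons kept their direction and side of the threshold, 19 lost it and 9 gained it. In 5 the direction turned, all in lists not past the threshold. The germline list turned without a filter on low counts (adjusted p = 0.925), the hypoxia list with limma-voom (adjusted p = 0.857) and limma-trend (adjusted p = 0.858), and the mesenchymal list with limma-voom (adjusted p = 0.985) and limma-trend (adjusted p = 0.838), and the cause was not tested. Of the named genes, 2226 comparisons were the same, 0 turned and 7 no longer passed, all against the 1.5-fold threshold (Cebpb, Tet2, Kdm5b, Cyc1, Cox7a2, Rrm2 and Ramp2).

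Replicate numbers gave no clear sign of pairing: the deviations of same-numbered libraries correlated by -0.05, -0.07 and 0.16, and not every library correlated best with its own number. With 3 libraries per group these correlations depend on each other, so they cannot show that pairing is absent. With a replicate block 4448 genes were higher and 4214 lower, and 10 lists passed, the glutamate, glutamine and TCA cycle list falling out (adjusted p = 0.0598). Folds of genes near 0 in a group depend on few counts.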

Other observations

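The families and tests in this part were chosen after the data were seen. Some families hold genes named above for their large change, such as Gria4, Grik3, St6gal2 and Sema5a. Their p-values therefore describe these data and are not independent tests. Of 8 gene families tested with camera, 5 passed with the preset correlation and 0 with an estimated one, where 2 were under an unadjusted p of 0.05. Glutamate receptor subunit genes were higher for 9 of 14 members and lower for 3 (camera adjusted p = 0.00013, adjusted p = 0.0922 with an estimated correlation). Besides Gria2, Gria4 and Grik3, the metabotropic receptor gene Grm5 rose from 3.18 ± 0.149 to 26.1 ± 4.19 CPM and Grin3a from 2 counts over the control group to 6.72 ± 0.358 CPM, whereas Grin2b fell from 4.24 ± 0.318 to 0.316 ± 0.088 CPM. Sialyltransferase genes were higher for 11 of 15 and lower for 1 (camera adjusted p = 5.74e-05, adjusted p = 0.124 with an estimated correlation), among them St8sia1, from 6.76 ± 0.364 to 81.5 ± 2.85 CPM, and St3gal6, from 8.35 ± 0.431 to 98.5 ± 4.83 CPM. Cadherin genes were higher for 8 of 13 and lower for 2 (camera adjusted p = 0.00142, adjusted p = 0.124 with an estimated correlation), with the neural cadherin gene Cdh2 rising from 13.4 ± 1.58 to 83.3 ± 5.82 CPM (mean ± SD, n = 3, edgeR). Clustered beta protocadherin genes were lower for 15 of 20 and higher for 2 (camera adjusted p = 0.025, adjusted p = 0.124 with an estimated correlation). These genes are similar in sequence and can share reads. Integrin genes were lower for 13 of 20 and higher for 4 (camera adjusted p = 0.0398, adjusted p = 0.158 with an estimated correlation), and with 3 genes of integrin-binding proteins counted in, as first tested, the family did not pass (camera adjusted p = 0.0888). Semaphorins, snoRNAs and interferon regulatory factors did not pass (camera adjusted p = 0.155, 0.106 and 0.155).

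Whole chromosomes differed slightly in median, and the share of changed genes ran from 56.2% on chromosome 16 to 72.2% on chromosome 14. Of 20 chromosomes tested, the lowest median log2 fold changes were -0.37 on chromosome 8, -0.33 on chromosome 14 and -0.27 on chromosome 10, and the highest 0.22 on chromosome 9 and 0.23 on chromosome 18 (permutation p = 1e-04 each, the smallest that 10000 shuffles can give, adjusted p = 2e-04). Genes of a chromosome are not independent replicates. Neighbouring genes also changed together. Among genes with a mean of at least 10 CPM, the SD of medians over 15 neighbours was 0.263. The highest SD in 1000 shuffles of position was 0.146. Around Bcat1 the local median of 51 genes was 0.24.

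With 3 libraries in each group, the 10 splits are too few for a share under 0.05. The real split gave 8735 changed genes and 11 lists, and 1 split, the real one, gave as many genes. The highest of the others was 0 genes with edgeR, which called 13 to 122 genes there at an unadjusted p under 0.05, and 12 lists in the split that joined Bcat1-KO replicates 1 and 2 with control replicate 2, so 2 splits, counting the real one, gave as many lists. Every other split keeps more knockout libraries on one side than on the other. Each side there also holds both knockout and control libraries, so the difference between the groups widens the spread within a side. The 0 genes called there can come from that spread, and they do not test the real split.

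A set of 48 genes had a level below 0.1 CPM over the control group and of 2 CPM or more over the knockout group, and 43 genes the reverse. A difference in library depth between groups is argued against by the totals. They ran from 29543157 to 37800648 counts, a far smaller gap than that between 0.1 and 2 CPM. After all libraries were thinned to the lowest total, 87 of the 91 remained in their class. So slight a thinning could remove few genes, so it adds little. Cells of another type in one group would bring their abundant transcripts along. Markers picked for this stayed below the 2 CPM that each of the 91 has by definition. The highest means were 0.468 CPM among C1qa, C1qb, C1qc, Tyrobp, Lyz2, Fcer1g, Aif1, Csf1r and Ptprc, 0.401 CPM among Pecam1, Cdh5, Cldn5, Kdr, Flt1 and Emcn, and 0.405 CPM among Col1a2, Dcn and Lum. These values argue against macrophages, endothelial cells and fibroblasts that express these markers, in either group. Other members of these lists reached higher means, Col3a1 and Col1a1 with 60.4 and 17.7 CPM in the control, Thy1, Ramp2 and Egfl7 with 69.5, 34.6 and 8.51 CPM in the knockout, and Cd68 with 3.02 CPM in the knockout and 3.32 CPM in the control. They were not among the markers picked, so cells that express only these members stay open. Mural cells are argued against for the genes on in the knockout, where Acta2, Tagln, Myh11, Rgs5 and Pdgfrb reached at most 0.261 CPM (Myh11). For the genes on in the control, Acta2 among them, mural cells stay open, since Pdgfrb reached 4.54 CPM there. A dosage change of whole chromosome blocks is argued against as the main source, since 6 of the 91 had neighbours with a median log2 fold change of at least 1 in the same direction. A median over 5 neighbours on each side cannot show a loss or gain of only a few genes, nor a shift below that limit. Such changes were not tested. Some of the 91 lay close together, such as Smim20 and Gm45495 on chromosome 5 (starts 53267083 and 53281810), both off in the knockout. Brinp2 and Astn1 on chromosome 1 (starts 158245269 and 158362273) were both on in the knockout. A separate history of the 2 cell lines before harvest could also give such genes and stays open with an effect of Bcat1, because 0 samples have a label that names a clone, and the 2 cannot be told apart here.

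TMM factors lay between 0.984 and 1.02, too close to 1 to give the rise of the chromosome 7 stretch (median log2 fold change 2.55). They argue against an effect of normalization. The median of -0.0828 over the 40 flanking genes adds no test, since the borders were set after the values were seen. Switching on of silent genes alone is argued against by the median of 2.78 over the 12 members of the stretch with at least 10 CPM in the control. A chance run is argued against by 0 of 1000 shuffles of position reaching its highest median over 15 neighbouring genes. The log2 fold changes of its members with at least 10 CPM in the control spanned 4.26 units. The lowest was 0.20 for Arhgap35, near an edge of the stretch, and the next lowest 1.76 for Slc1a5. This span argues against an equal gain in dosage as the only cause, but RNA does not show whether copies rose equally. A gain in copies that arose in the knockout line, equal or unequal, or a change in regulation of the stretch may still account for the joint rise. Copy number was not measured.

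For the lower genes of MHC class I antigen presentation, a local change of the cluster on chromosome 17 is argued against as the whole cause. Of the 11 members elsewhere, 9 were also lower, with a median log2 fold change of -0.64. Reads shared between similar H2 genes are argued against as the whole cause, since 10 of the 13 members that are not H2 genes were lower. H2-T23, H2-K1 and H2-D1, on chromosome 17, fell more, with log2 fold changes of -2.85, -2.30 and -2.09. For these H2 genes a local change and shared reads both stay open. The knockout and a difference between lines that arose before harvest both remain open and untested.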
